A study of Caenorhabditis elegans with 2 samples.

How the data were processed

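The data are peak lists from chromatin immunoprecipitation of GFP-tagged F44E2.7 followed by sequencing, from 2 biological replicates of transgenic L4 larvae of Caenorhabditis elegans (strain OP381), which form 1 group. Per the labels, chromatin was sonicated to a size range of 200 to 800 and peaks are on the ce11 assembly. The aligner, the peak caller and their settings are not given in the sources used here. The labels name a possible control experiment, and how it was used is not given in the sources used here.

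There were 8 peak lists, 4 thresholded and 4 ranked by the irreproducible discovery rate (IDR), a measure of how consistently a peak ranks in a pair of lists. Per the accompanying file notes, lists of the whole series derive from both replicates and those of a sample from that replicate alone. Each list has the authors' score, a whole number capped at 1000 that follows the logarithm of the IDR. The deposited signal value of each peak is the authors' enrichment measure on an unstated scale, used only within a list. The deposited -log10 q and -log10 IDR values were used as given. Every thresholded peak was in its ranked list at an IDR of 0.01 or lower, so the authors' threshold equals 0.01. In 1 ranked list of the whole series, 63.4% of the first matched signals recurred in the ranked list of replicate 1 and 20.5% in that of replicate 2, and 66.5% of the second recurred in that of replicate 2 and 20.6% in that of replicate 1. These signals were therefore taken to be those of the replicates, and the other series-level ranked list to come from pooled reads, which are inferences.

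Coordinates were compared with the WBcel235 genome, whose chromosome names and lengths fit the ce11 coordinates, and are given 1-based. Gene positions came from the Ensembl annotation and tRNA products from the RefSeq annotation. Peaks lay on 6 nuclear chromosomes. Symbols shared by several genes were counted once per gene.

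Shares were tested with exact binomial tests, gene lists with Fisher exact tests, and distances to non-coding genes with 10000 random placements of the summits within their own chromosomes. Medians were compared by permutation with 100000 resamples. Adjusted values follow Benjamini and Hochberg at 0.05, within each family. Replicates were compared by overlap of at least 1 bp. Promoter windows ran from 1000 bp upstream to 200 bp downstream of protein-coding gene starts, and k-mers of 6 bases were counted in windows of 50 bp to either side of the summit, with flanks centred 300 bp away. Gene lists, 21 by symbol and 8 of cell type markers, were fixed before the data were examined, as were the tests of overlap, chromosomes, annotation, non-coding classes, gene lists, sequence and the transgene loci. Tests chosen later are named as such where they are given. The lists covered cytosolic and mitochondrial ribosomal proteins, cuticle collagens, histones, major sperm proteins, nuclear hormone receptors, homeobox genes, the proteasome, the respiratory chain, the vacuolar ATPase, heat shock genes, translation factors, aminoacyl-tRNA synthetases, splicing, neuropeptides, C-type lectins, detoxification, chemoreceptors, F-box and BTB-MATH genes, ubiquitin conjugation and Mediator. Named peaks were the 25 of highest signal in the pooled list that overlap a conservative peak, with the genes whose promoter window or body holds the summit, or else the nearest start. F44E2.7, unc-119 and up to 4 members per list, by signal, were added.

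The tests were checked on simulated lists. Of 200 summits planted at tRNA genes, 200 were recovered, as were 40 of 40 planted ribosomal protein genes, and 12 of 240 chromosome tests on random lists were below 0.05. The summits were planted inside the counted windows, so full recovery checks the counting only and not sensitivity. Random lists had uniform positions and did not imitate clustered peaks. With a word planted in 15% of windows, 6 of 6 planted 6-mers were called along with 5 others, all of which cover an end of the planted word. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

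Alternatives covered the conservative list, each replicate's list alone, an IDR of 0.01 that turned out to equal the deposited threshold, other windows, distances and expectations, merging of summits within 200 bp, and a Cochran-Mantel-Haenszel test over upstream intergenic length. IDR thresholds of 0.001 and 0.05, removal of peaks near tRNA genes, inclusion of peaks absent from the thresholded list, a tRNA pseudogene class, ncRNA genes apart from other classes, further B box comparisons and the lists used for the share of tRNA genes were added after the data were seen. No file holds counts, so no count model was fitted and depth was not estimated.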

Results

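Chromatin immunoprecipitation was carried out on whole Caenorhabditis elegans larvae at the L4 stage, 48 hours old, that carried a transgene encoding F44E2.7 fused to EGFP. The labels' description gives an antibody against GFP, while their antibody field names F44E2.7, and no untagged sample was analysed here. The labels describe 2 biological replicates of 1 group. There was no second condition, and the comparisons below set the peaks against the genome, the annotation and each other. No file used here gives read counts, so sequencing depth is unknown. Every signal value quoted is the authors' own value for that peak and ranks peaks within a list only. Intervals on shares are exact Clopper-Pearson 95% intervals and cover counting error over peaks only. Peaks are not independent replicates, so p-values across peaks describe these lists.

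How many sites each list held, and how far the replicates shared them, was examined first. The thresholded list made from both replicates held 896 peaks and is called the pooled list here. The conservative list held 864 peaks, and 689 of the pooled peaks overlapped one of them. The list of replicate 1 held 178 peaks and that of replicate 2 held 319, a ratio of 1.79. Of the replicate 1 peaks, 115 of 178 (64.6%, interval 57.1 to 71.6%) overlapped a replicate 2 peak, and 114 of 319 replicate 2 peaks (35.7%, interval 30.5 to 41.3%) overlapped a replicate 1 peak. Random placement of a list within its chromosomes gave at most 4 meeting peaks in either direction (permutation of positions, one-sided p = 1e-04, the smallest that 10000 placements can give). In the pooled list, 114 peaks were in both single-replicate lists, 237 in one of them and 545 in neither. Peaks in both lists had a median signal of 159 (interquartile range 132 to 184), against 77.9 (71.8 to 85.3) for peaks in neither. Membership of those lists itself depends on signal, so this difference is given as a description with no p. Across 891 pooled peaks with a pair of matched signals, taken to be those of the replicates, Spearman's rho was 0.275 and Pearson's r was 0.650.

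The clearest feature of the pooled list was its position at genes for small structural RNAs. tRNA genes, which RNA polymerase III transcribes, lay within 200 bp of 226 of 896 summits (25.2%, interval 22.4 to 28.2%), and random placement gave a mean of 2.47 summits. snoRNA genes, whose products guide the modification of other RNAs, lay near 50 summits (5.58%, against a random mean of 0.179%). snRNA genes lay near 15 summits against 0.557, and genes annotated as other ncRNA lay near 223 against 31.6. Of those 223 summits, 148 were also near a tRNA gene, and 50 lay near none of the tRNA, tRNA pseudogene, snoRNA or snRNA genes. In a test added after seeing the data, those 50 of 594 summits stood against a random mean of 18.5 (permutation of positions, one-sided p = 1e-04). With all 896 summits placed instead, the random mean was 29.6 and the highest count 51 (permutation of positions, one-sided p = 3e-04). Each of the tRNA, snoRNA, snRNA and ncRNA classes exceeded all 10000 placements (permutation of positions, one-sided, adjusted p = 2.25e-04 over 9 classes, the smallest they can give here). Most of the list, 544 of 896 summits (60.7%), lay near none of these classes or the tRNA pseudogenes. miRNA genes, namely let-7, mir-51, mir-54 and mir-4936, lay near 4 summits (0.446%, against a random mean of 0.112%; permutation of positions, adjusted p = 0.0335). That call ended in each single-replicate list (permutation of positions, adjusted p = 0.524 for replicate 2 and 0.349 for replicate 1). Summits near lincRNA genes (4, at linc-44, linc-90, linc-128 and linc-163) and antisense RNA genes (2, at anr-5 and W10G6.5) did not pass (permutation of positions, adjusted p = 0.437 for each). The miRNA, lincRNA and antisense RNA genes are named after their values were seen. piRNA genes, of which 15363 are annotated, lay near 5 summits (0.558%, against a random mean of 2.57%), and the one-sided test for an excess gave p = 1 by permutation of positions. No summit lay near the 20 annotated nuclear rRNA genes (0 of 896, interval to 0.411%). The random mean there was only 0.162 summits, so this count cannot show an absence.

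**Figure D1:**
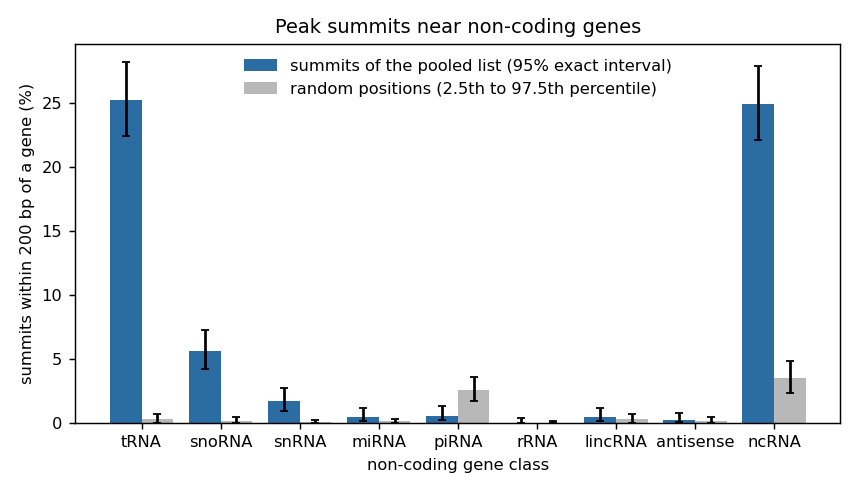
Share of the 896 pooled summits within 200 bp of a gene of each non-coding class, in percent (blue, 95% exact interval), beside the mean of 10000 random placements within chromosomes (grey, central range of the placements). tRNA genes lay near 25.2% of summits against 0.276% of random positions.

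Of 612 nuclear tRNA genes, 250 (40.8%, interval 36.9 to 44.9%) had a summit within 200 bp. Genes for tRNA-Cys stood apart among the products, with 12 of 13 genes at a summit (Fisher exact test against the other tRNA genes, odds ratio 18.2, adjusted p = 0.00318 over 21 products). tRNA-Gly genes had a summit at 30 of 55 and tRNA-Gln genes at 6 of 27, and neither passed the adjustment (adjusted p = 0.271 for each). The X chromosome carries 276 of the 612 genes, and 106 of them (38.4%) had a summit. The share was 33.8% on chromosome IV, 35.9% on V, 40.4% on II and 50% on I, with 36 of 64 genes on III, and differences between chromosomes were not tested. This share of genes, its products and chromosomes, and the signal and replicate support of tRNA peaks were examined after the tRNA count was seen. Peaks near tRNA genes had a median signal of 95.2 against 81.5 for the others (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give), and 33 of the 226 were in both single-replicate lists, against 81 of 670 other peaks (Fisher exact p = 0.356). In the list of replicate 2 alone 19.8% of tRNA genes had a summit, and in that of replicate 1 alone 9.48%.

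At snoRNA genes the peaks were among the highest of the list. Summits near snoRNA genes had a median signal of 136 (interquartile range 94.7 to 185), against 84.4 (74.7 to 101) elsewhere (permutation p = 1e-05). Of the 25 named peaks of highest signal, 12 lay within 200 bp of a snoRNA gene, compared with 38 of the other 871 (Fisher exact odds ratio 20.2, p = 7.17e-10). Of the remainder of the 25, 5 lay near tRNA genes. The first of them by signal (413, ce11 chromosome V, 8500470 to 8500662, summit at 8500571) fell in an intron of pxn-1, 8 bp upstream of the snoRNA gene ZK994.7. The next (411, chromosome V, 12303544 to 12303740) fell in frm-7, inside the snoRNA gene C51F7.4 and 60 bp upstream of C51F7.3. Summits stood upstream of the snoRNA 5′ end at 42 of 51 genes, with a median position of -39 bp (interquartile range -55.5 to -6.5). At tRNA genes the median position was 20 bp inside the gene (-2 to 45), and at 67 of the 250 genes the summit stood upstream, where 1 summit can count for several genes. The snoRNA median minus the tRNA median was -59 bp (permutation p = 1e-05). These snoRNA comparisons were chosen after the peak positions were seen.

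**Figure D2:**
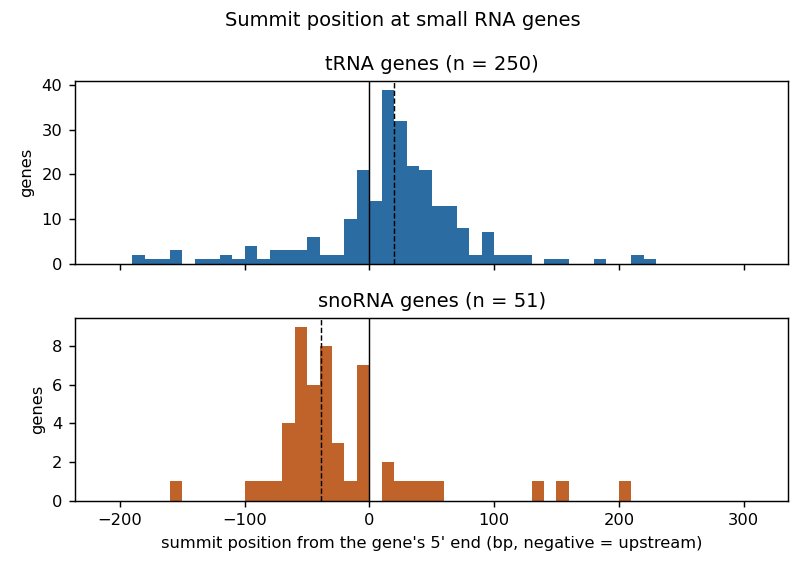
Position of the summit relative to the 5′ end of each gene with a summit within 200 bp, in base pairs, for 250 tRNA genes (top) and 51 snoRNA genes (bottom). Solid lines mark the 5′ end and dashed lines the medians, 20 bp for tRNA genes and -39 bp for snoRNA genes.

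Other structural RNA genes were also at summits, and they are named here after their values were seen. rpr-1, the RNA of RNase P (chromosome I, 13463955 to 13464207), had a summit at its first base with a signal of 317, inside ints-8. Both srpr-1 genes on chromosome III, which encode the RNA of the signal recognition particle, had a summit within 200 bp, with signals of 105 for srpr-1.2 and 97.7 for srpr-1.1. mrpr-1, the RNA of RNase MRP, had a summit 21 bp inside the gene with a signal of 88.3. Of 19 annotated sls-2 genes, which encode spliced leader RNA, 5 had a summit within 200 bp (sls-2.1, sls-2.2, sls-2.4, sls-2.8 and sls-2.9), and none of the 12 sls-1 genes did.

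Whether peaks fell at protein-coding promoters was examined next. Windows from 1000 bp upstream to 200 bp downstream of protein-coding gene starts held 256 of 896 summits (28.6%, interval 25.6 to 31.7%), where such windows cover 21.5% of the nuclear genome (two-sided exact binomial p = 5.22e-07). Of these 256 summits, 51 lay near a tRNA gene. In the replicate 1 list the share was 24.2% and did not pass the exact binomial test (p = 0.363). Exons outside protein-coding sequence and UTRs held 185 summits, 6.98 times their share of the genome, and 135 of those lay near a tRNA gene. Introns held 168 summits (18.8% against 31.0% of the genome) and coding exons 117 (13.1% against 19.6%), both lower (exact binomial, adjusted p = 3.40e-16 and 6.41e-07). Intergenic DNA held 149 (16.6% against 21.6%, exact binomial, adjusted p = 2.61e-04), and UTRs held 21 (2.34% against 3.40%, adjusted p = 0.0959). These shares sum to the whole, so the tRNA summits lower the others. Without summits near tRNA genes, an alternative chosen after seeing the data, coding exons held 17.2% and intergenic DNA 19.6% of 670, and neither call remained (exact binomial, adjusted p = 0.179 and 0.246). Introns then held 22.2%, other exons 7.46% and promoter windows 30.6%, and each passed (exact binomial, adjusted p = 9.94e-07, 3.92e-08 and 9.64e-08). Gene starts with a divergent neighbour within 1000 bp had a summit at 76 of 3491, against 225 of 16482 other starts (Fisher exact odds ratio 1.61, p = 7.19e-04). A single summit can count for both starts of a divergent pair, as at tasp-1 and K01G5.10. This raises the divergent count, and the test treats paired starts as independent, so its p is too small. Promoter-window peaks had a median signal of 84.9 and other peaks 85.2 (permutation p = 0.801).

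Cytosolic ribosomal protein genes, whose products build the ribosome, had a promoter-window summit more often than other genes: 9 of 81 (11.1%) against 292 of 19892 (1.47%; Fisher exact odds ratio 8.39, adjusted p = 1.04e-04 over 29 lists). rpl-3 (chromosome III, summit at 3867567, signal 289), rpl-35 (signal 174), rpl-20 (signal 141) and rpl-15 (signal 137) were the strongest, and 1 of the 9 summits lay near a small RNA gene. Heat shock genes had 4 of 22 (18.2%; Fisher exact odds ratio 14.7, adjusted p = 0.00289), namely hsp-60, which encodes a mitochondrial chaperonin, hsp-1, hsp-3 and hsp-110, with 2 of these summits near a small RNA gene. Chemoreceptor genes, which neurons use to sense chemicals, had a summit less often than other genes, at 5 of 1309 (0.382%; Fisher exact odds ratio 0.238, adjusted p = 0.00132). These were sre-23 (signal 230, with the summit also beside the snoRNA gene ZK265.10), srh-269, sre-21, srz-58 and srh-34, and 3 of the 5 summits lay near a small RNA gene, those of srh-269 and srz-58 near a tRNA gene. The heat shock and chemoreceptor calls were lost in each single-replicate list (Fisher exact, adjusted p = 0.955 for both in replicate 2, and 0.899 and 1 in replicate 1). Both calls were also lost in the pooled list with windows of 500 bp upstream to 100 bp downstream, and at an IDR of 0.001. The ribosomal protein list passed in both single-replicate lists, at 7.41% of its genes in replicate 2 and 4.94% in replicate 1 (Fisher exact, adjusted p = 1.64e-04 and 0.00261).

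The other 18 lists by symbol did not pass the adjustment. Respiratory chain genes had 3 of 40, namely cox-5A (signal 144), cox-6A and cyc-2.1, splicing genes 3 of 52 (rsp-1, rsp-2 and snrp-200), Mediator genes 2 of 20 (mdt-17 and mdt-26), and homeobox genes 3 of 78 (ceh-2, ceh-43 and ceh-38). Cuticle collagens had 2 of 176 (col-185 and col-104), nuclear hormone receptors 2 of 269 (nhr-255 and nhr-47) and detoxification genes 2 of 185 (cyp-43A1 and gst-27). Mitochondrial ribosomal proteins (mrpl-23), histones (his-59), the proteasome (rpn-3), the vacuolar ATPase (vha-13), aminoacyl-tRNA synthetases (ears-2), F-box and BTB-MATH genes (fbxb-40) and ubiquitin conjugation genes (ubc-6) each had 1. Major sperm proteins, translation factors, neuropeptides and C-type lectins had 0. Of the cell type markers, the intestinal list had 1 of 27 (asp-1) and the developmental timing list 1 of 12 (mab-10). Neuronal, muscle, epidermal, germline, cell cycle and pharyngeal markers had 0. None of the 8 marker lists passed. The marker lists with 0 held 8 to 43 genes, and those of major sperm proteins and translation factors 31 and 39. Only about 1.51% of other genes had a summit, so a count of 0 in lists this short cannot show an absence.

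Chromosome IV held fewer peaks than its length predicts, 117 against 156 (13.1%, interval 10.9 to 15.4%; exact binomial, adjusted p = 0.00252 over 6 chromosomes). Chromosomes I, II, III, V and X did not pass against length, where the 213 peaks of V include a crowded stretch described below. Against the share of gene starts, II and IV held fewer peaks than expected (exact binomial, adjusted p = 0.00584 and 0.00989). III and X held more (exact binomial, adjusted p = 0.00989 and 5.87e-04). The replicate 1 list did not pass for chromosome IV (13.5%, exact binomial, adjusted p = 0.595). Chromosome X held 164 peaks against 158, of which 94 lay near tRNA genes. Without peaks near tRNA genes, an alternative chosen after seeing the data, X held 10.4% of 670 peaks and fell below its 17.7% of the genome (exact binomial, adjusted p = 1.63e-06). Pooled summits were crowded near 1 end of chromosome V, as between 19998396 and 20217920. The binomial tests count each of these as independent, and no test was repeated without this stretch. A general feature of the autosomes is therefore not shown by the next share. The middle of the autosomes, the central 50% of their length, which leaves out the crowded stretch, held 323 of 732 autosomal summits (44.1%, interval 40.5 to 47.8%; exact binomial p = 0.00166). That share was 47.4% in the replicate 2 list (exact binomial p = 0.449) and 50.4% in the replicate 1 list (exact binomial p = 1).

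**Figure D3:**
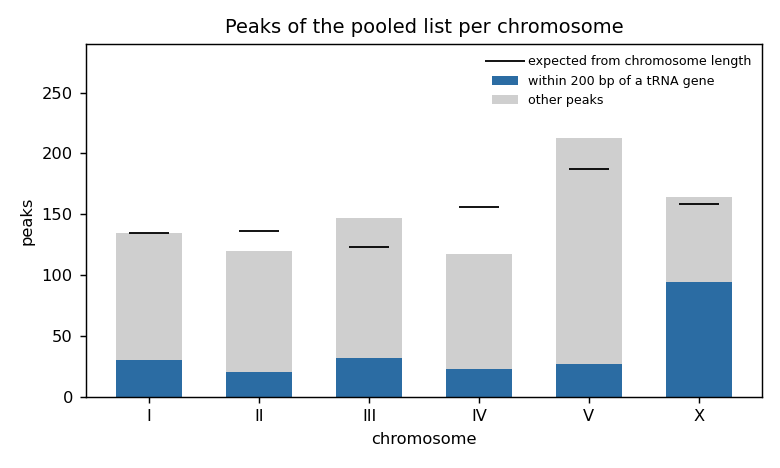
Peaks of the pooled list per chromosome, split into those within 200 bp of a tRNA gene (blue) and the others (grey), with the number expected from chromosome length (black marks). On X, 94 of 164 peaks lay near a tRNA gene.

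The DNA at the summits was rich in G and C. Windows of 50 bp to either side of the summit had a mean GC content of 49.7% (SD 8.61 over 896 peaks), against 36.0% (SD 7.38) in flanks centred 300 bp away, a difference of 13.7 percentage points (sign-flip permutation p = 1e-05). The B box pattern GTTCRANNC, the internal promoter element of tRNA genes, was in 207 of 896 summit windows (23.1%) against 60 of 1792 flanks (3.35%; Fisher exact odds ratio 8.67, p = 4.87e-54 adjusted over the list alone). It was in 152 of 226 windows near tRNA genes. Of 2080 canonical 6-mers, 614 were more frequent at summits and 356 less frequent, including all 36 made of A and T only. CGAACC was in 16.2% of summit windows against 2.51% of flanks (Fisher exact odds ratio 7.50, adjusted p = 8.90e-34). Its reverse complement, GGTTCG, overlaps the start of the B box pattern, so CGAACC is not separate evidence. Both partly restate that many summits lie at tRNA genes. Windows near tRNA genes hold related sequences and are not independent, so the p-values for CGAACC and the B box are too small. GAGAG was in 26.0% against 13.9% and TGATAA, the core of a GATA factor site, in 5.47% against 9.82% (Fisher exact, adjusted p = 1.83e-13 and 1.71e-04 over 14 patterns). Because the flanks are lower in GC, differences in 6-mers and patterns can follow base composition. Neither GAGAG nor TGATAA was compared with windows of the same GC content.

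**Figure D4:**
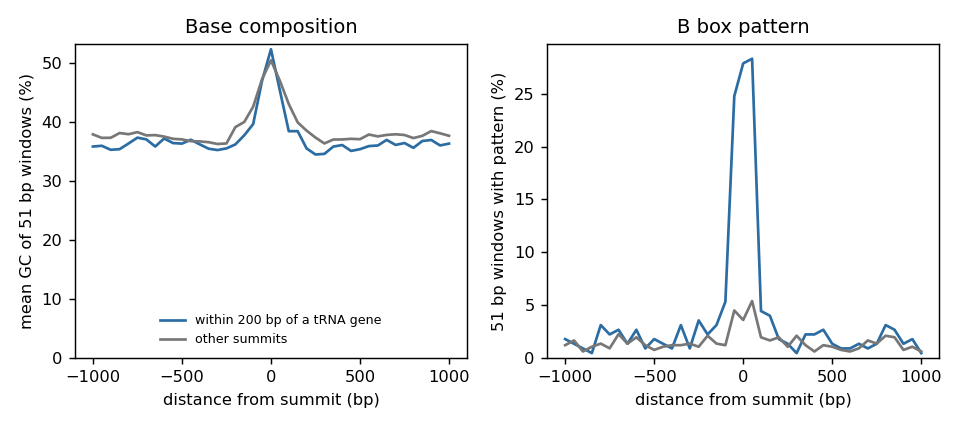
Mean GC content (left) and share of windows with the B box pattern (right), both in percent of 51 bp windows, against distance from the summit in base pairs, for 226 peaks within 200 bp of a tRNA gene (blue) and 670 others (grey). GC rises at the summits of both sets.

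The strain carries extra copies of a clone with F44E2.7 and of unc-119(+), so both loci were examined. Within 20 kb of F44E2.7 (III, 8845855 to 8848472) the pooled list had 1 peak, with its summit at 8865644, 17172 bp from the gene, and a signal of 83.7. Among 10000 randomly drawn protein-coding genes 27.2% had as many (permutation of genes, one-sided p = 0.272). With the peaks that the thresholded list leaves out included, an alternative chosen after seeing the data, there were 4 peaks (permutation of genes, p = 0.0117). The added peaks lay close together, 14704 to 15405 bp from the gene, with repeated words in 68.6 to 100% of their length. They may therefore be 1 site, and whether extra copies of the clone give it was not tested. No pooled peak lay within 20 kb of unc-119 (III, 10902641 to 10908935).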

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

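The comparisons of signal, position and neighbours and the count near F44E2.7 were chosen only after the left-out peaks were seen, and the test of repeated sequence was set before its result was seen. The ranked list contained peaks that the thresholded list leaves out, and most comparisons do not use them. At an IDR of 0.01 or lower, 91 peaks of the ranked pooled list were absent from the thresholded list, and the highest signal among them was 3804.96, on chromosome X at 15810947 to 15811190 in intergenic DNA. Of the 91, 11 exceeded the highest signal of the 896 kept peaks, 413. Their median signal was 135, against 85.1 for the kept peaks (permutation p = 1e-05). None lay within 200 bp of an annotated non-coding gene, 1 lay in a promoter window, and 66 of 91 had another left-out summit within 5000 bp, against 269 of 896 kept peaks with another kept summit (Fisher exact odds ratio 6.15, p = 3.25e-15). Exclusion of repeated sequence by the authors is a candidate explanation. The left-out peaks held a mean of 80.3% 32-base words that occur more than once in the genome, against 15.6% for kept peaks, a difference of 64.7 percentage points (permutation p = 1e-05). Why those peaks were left out is not given in the sources used here, and no biological explanation of it was tested.

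Of the left-out peaks, 3 lay within 20 kb of F44E2.7, at 14704 to 15405 bp from the gene, with signals of 241, 135 and 56.0 and repeated words in 86.6%, 100% and 68.6% of their length.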

How the results depend on the processing

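The IDR of 0.001 or 0.05, the removal of peaks near tRNA genes, the inclusion of left-out peaks and the alternatives for the share of tRNA genes were chosen after seeing the data. Under settings fixed in advance, 338 comparisons, results never past the threshold included, stayed on their side of it or within their spread, 12 lost the call, 3 gained it, 8 moved and 1 reversed. Of the 338, 51 used an IDR of 0.01, which repeats the deposited threshold and tests nothing. Under settings added later, 141 stayed, 7 lost the call, 4 gained it, 12 moved and 1 reversed. The tRNA, snoRNA, snRNA and other ncRNA classes and the ribosomal protein list stayed past the threshold in every alternative run for them. Depth is unknown, so what it limits was not assessed.

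With each replicate left out in turn, the share of summits in autosome centres was 47.4 to 50.4%, and at 50.4% its direction turned. Chromosome IV held 11.6 to 13.5% of peaks, with 0 to 1 chromosomes called, and promoter windows held 24.2 to 27.6%. miRNA genes lay near 0.313% of 319 and 0.562% of 178 summits, the smallest non-zero shares that lists of that length can give. A count of 1 gene list passed (3 in the report), with heat shock genes at 4.55% of 22 and chemoreceptors at 0.0764 to 0.306% of 1309. Higher 6-mers numbered 222 to 375 (614 in the report), and 9.48 to 19.8% of tRNA genes had a summit. These lists hold fewer peaks, and the cause was not tested further.

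At an IDR of 0.001, the pooled, conservative, replicate 1 and replicate 2 lists held 190, 174, 51 and 89 peaks. Chromosome IV then held 13.7%, the centres 49.6%, and miRNA genes lay near 0.526% of 190 pooled summits, again the smallest non-zero share. The list count was 1, with heat shock genes at 4.55% and chemoreceptors at 0.0764%, 262 higher 6-mers and 3 annotation classes called (5 in the report). With windows of 500 bp upstream to 100 bp downstream, 1 list passed, and the calls for heat shock genes (9.09%) and chemoreceptors (0.306%) were lost. Centres narrowed to 33.3% of the autosomes held 30.5%, and the call was lost (exact binomial p = 0.108). Against gene starts, 4 chromosomes were called (II and IV lower, III and X higher). Without peaks near tRNA genes, 4 chromosomes were called, III and V above and IV and X below their share of the genome. V holds the crowded stretch. The share on X reversed, to 10.4%, and 3 annotation classes were called. With left-out peaks included, miRNA genes lay near 0.405% of summits and 4 peaks lay near F44E2.7. At an IDR of 0.05, 54.2% of tRNA genes had a summit. Over ranked peaks at an IDR of 0.01 or lower, rho was 0.405. The cause was not tested for any of these.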

Other observations

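The test of ribosomal protein genes against tRNA genes and the test of the B box away from tRNA genes were chosen only after the tRNA result was seen, as were the further B box comparisons. tRNA pseudogenes, a class added after seeing the data, lay near 16 summits against a random mean of 0.87. The B box pattern was in 18 of 50 summit windows near snoRNA genes and in 29 of 544 windows near none of the tRNA, tRNA pseudogene, snoRNA, snRNA or other ncRNA classes (Fisher exact p = 1.63e-09).

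tRNA genes stood at 226 of 896 summits, but at no more than 14 windows in any of 1000 draws of genomic windows matched on GC, which argues against GC content as the whole cause. Of 143 single-copy tRNA genes, those with no gene or pseudogene of identical full sequence, 44 had a summit, and random placement gave at most 5. Copies that differ by a few bases can still share reads, and a summit within 200 bp can belong to a neighbouring tRNA gene. Reads shared between copies therefore stay open as a contribution. Single-copy genes had a summit less often than tRNA genes with a copy (30.8% against 43.9%, Fisher exact p = 0.00638). A general enrichment at strongly transcribed genes stays open: ribosomal protein genes had a promoter-window summit at 11.1%, below the 40.8% of tRNA genes within 200 bp (Fisher exact p = 3.51e-08) but above the 1.47% of other genes. Enrichment at tRNA genes without the tagged protein stays open too, since no untagged sample was analysed here, and no biological explanation of the tRNA pattern was tested.

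The shorter list of replicate 1 may in part reflect sites of replicate 2 that fell below its threshold. Of the 205 replicate 2 peaks that overlap no thresholded replicate 1 peak, 190 (92.7%) overlapped a peak of the ranked replicate 1 list, where 1000 random placements gave a mean of 30.5% and at most 86 peaks. That ranked list is permissive, with 65299 peaks over 16.4% of the genome, and the placements were uniform. The overlap therefore exceeds uniform placement but cannot show that the sites are the same. Of the 178 replicate 1 peaks, 115 overlapped a replicate 2 peak, and the others were not sought in the ranked replicate 2 list. Whether depth separates the replicates stays open, since no file used here gives counts.

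A hypothesis is that the B box may itself be a sequence at which F44E2.7 is recovered, beyond annotated tRNA genes. In 655 summit windows over 500 bp from any tRNA gene or tRNA pseudogene, 50 (7.63%) held the pattern, against 3.05% of their flanks (Fisher exact odds ratio 2.62, p = 1.01e-05). Without windows near snoRNA, snRNA and other ncRNA genes, 29 of 544 (5.33%) held it, against 3.31% of flanks, and the test was no longer passed (Fisher exact odds ratio 1.65, p = 0.0595). Flanks are lower in GC, and genomic windows of the same GC content held it in a mean of 18.4 of 655 and 14.9 of 544 (1000 draws, one-sided permutation p = 0.001, the smallest they can give, and 0.002). Whether the pattern matters apart from small RNA genes stays open, and unannotated tRNA-like sequence was not excluded.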
